A study of Homo sapiens with 8 samples.

How the data were processed

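ATAC-seq was performed on 50-bp paired-end libraries of sorted H9 cells, 4 controls and 4 DJ-L1 knockdowns, per the labels' protocols. The submitters' processing notes name FastQC, MultiQC, Bowtie2 2.4.5, SAMtools 1.18, MACS3, bedtools 2.30.0 and the build hg38 (GRCh38), with no role or order. How insertion sites were shifted, how regions were called and which tool counted and tested them is not given in the sources used here.

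A single table held 171468 regions with their coordinates, counted from 1. Its 8 columns of libraries hold normalized signal deposited by the authors. At least 99.99% of these values were whole multiples, within 0.006, of the value of 1 read in that library, so reads per region were recovered by dividing by that step. The factors behind the steps average 1 over the libraries, from 0.649 in knockdown replicate 1 to 1.39 in control replicate 3, and did not equalize the sums over regions; that they follow the size of the whole library is inferred from the values. The deposited log2 columns give mean levels per group and a log2 fold change that is smaller than the difference of the group means, per the file headers and the values. The p-value columns are the authors' deposited p-value and adjusted p-value for each region. All per-sample columns were used.

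The test fixed before the data were examined assumed read counts, with a second form for normalized values. Since the values were normalized, the second form was used: limma 3.58.1 with a trended prior on log2(value + 1), with group as the only term, over all 8 libraries, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low regions. Regions with a mean of at least 10 over the 8 libraries were tested, 142936 regions or 83.4%, a limit set once the unit was known. The count test, edgeR 4.0.16 with TMM factors on the recovered reads, was an added alternative: regions changed in accessibility numbered 13500 with it, with 6629 for regions higher and 6871 for regions lower. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were also used.

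The normalized value of 3 reads lay between 2.15 and 4.62 across libraries, which limits what can be read from regions near that level. Within groups, pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom between 1.06 and 1.50. The highest values belonged to pairs with knockdown replicate 1. All 8 libraries entered the fit separately, but technical libraries can differ in this way too, so these values do not show independent replication. The procedure was tested on simulated data drawn at the real depths. With no effect it called 0 of 141763 regions. With 200 changed regions, 50 at each fold, it called 86% of those raised 2-fold, 42% of those raised 1.5-fold, 66% of those lowered to 0.5 and 22% of those lowered to 0.667, with 2 false calls over 141693 regions. The simulation gave all regions a common dispersion taken from the controls (0.00295), with no trends between libraries. With so few changed regions the adjustment is also stricter than with the 12534 calls of the real fit. These rates, and the 0 calls with no effect, therefore describe the simulation and not the real data.

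Genes were placed from a RefSeq gene table of GRCh38.p14. A region within 1 kb of either end of a protein-coding gene is called a gene-end region and stands in for a promoter, since strand and transcription start sites were not used here; this proxy also takes in 3' ends. Where a gene had several such regions, the one with the highest mean was used. A set of 15 lists of 374 genes were fixed before the data were examined (core, naive and primed pluripotency, 8-cell genome activation, trophoblast, hypoblast and endoderm, mesoderm, neural ectoderm, RNA polymerase I and ribosome biogenesis, cytosolic ribosomal proteins, p53 targets, integrated stress response, HOX genes, LINE1 and heterochromatin regulators, nuclear lamina and nucleolar tethering), and all 374 genes matched the table. A gene-end region was tested for 298 of them, and called list members are counted among those. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, with fry, and by exact permutation of the mean over the list. Set means over chromosomes were compared by two-sided exact permutation over 70 arrangements of the libraries.

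The regions named were also fixed by rule before the data were examined: the 10 largest changes in each direction among called regions whose groups did not overlap and whose higher group averaged at least 20, with 1 region per gene; the 5 smallest p in each direction; and up to 4 members of each list with the smallest p. Fits with other scalings, filters, thresholds, pseudocounts and tests, with the replicate number as a block and with each library left out were also run. Thinning to equal depth, the trend on gene density, TMM factors, the edgeR tests, the HOX clusters with and without gene ends, shared regions counted once, the comparison of gene ends within deciles of mean level (Mantel-Haenszel) and the estimated correlation at a mean of at least 50 were chosen after seeing the data. Regions in LINE1 repeats, unplaced contigs and GC content were not analysed here.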

Results

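Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in naive H9 cells, an established human embryonic stem cell line kept in a medium that holds it in a naive state. The cells were transfected with guide RNA plasmids and sorted 48 h later. In 4 libraries the guides were directed at LINE1 retrotransposon copies in the distal junctions that flank the ribosomal DNA arrays (DJ-L1 knockdown), and 4 libraries were controls. Both groups received 10 nM DZNep, which inhibits S-adenosylhomocysteine hydrolase and with it histone methylation, and 5 nM trichostatin A, a histone deacetylase inhibitor. The comparison asks whether targeting these copies changed accessibility across the genome. The targeted copies themselves were not analysed here, so the libraries carry no check of the knockdown. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

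The deposited table gave normalized read counts for 171468 regions in each library. The reads behind them summed to 8.20, 8.15, 8.90 and 6.07 M in control replicates 1 to 4 and to 3.72, 3.91, 6.28 and 4.57 M in knockdown replicates 1 to 4. The group means were 7.83 ± 1.22 and 4.62 ± 1.17 M (SD, n = 4 each, two-sided exact permutation p = 0.0571). After the authors' scaling, the sum over all regions was 6.42 ± 0.0522 M in the controls and 5.90 ± 0.197 M in the knockdown, 4 libraries each, a difference of -8.21% (exact permutation p = 0.0286, the smallest that 70 arrangements allow). The strongest decile of regions held 39.9 ± 0.653% of this signal in the controls and 37.5 ± 1.94% in the knockdown (exact permutation p = 0.0286, n = 4 each), with 34.6% in knockdown replicate 1.

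**Figure D1:**
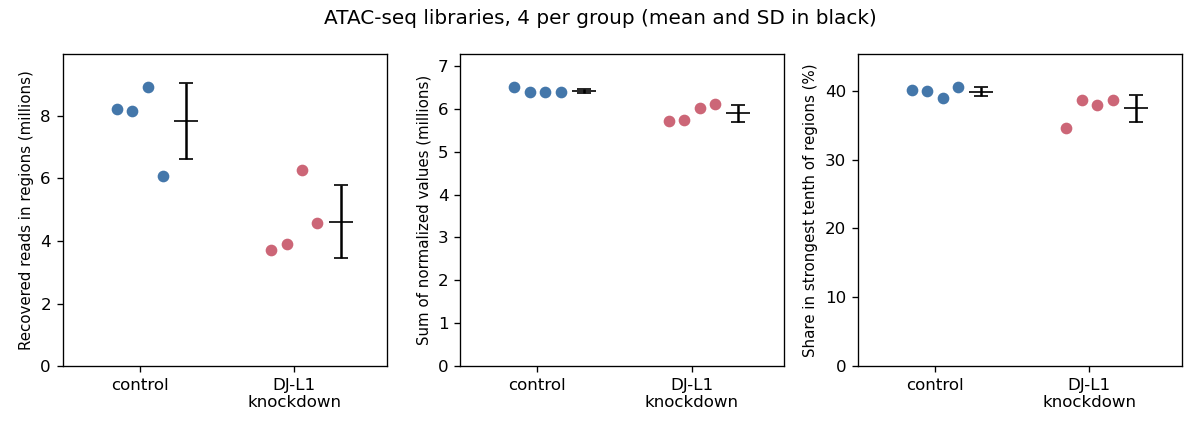
Reads in regions, sum of the normalized values and share of that sum in the strongest decile of regions, for each library (points) with the mean and SD of the 4 libraries per group (black). The knockdown libraries had fewer reads on average (4.62 against 7.83 M) and lower normalized sums (5.90 against 6.42 M).

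Accessibility differed between the groups at 12534 of 142936 tested regions (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 2930 were higher and 9604 were lower in the knockdown. The median log2 fold change was 0.79 among the higher regions and -0.64 among the lower ones, and 1793 regions differed by at least 1 on the log2 scale, 616 higher and 1177 lower. The balance between higher and lower regions depended on the scaling. At the deposited scaling 23.4% of the changed regions were higher, with TMM factors 44.6% (4438 higher, 5511 lower), with DESeq2 size factors 45.9%, with loess scaling on mean level 47.4% and with scaling to the total in regions 55.0% (5674 higher, 4639 lower). Each of these scalings raised the log2 fold change of 100% of the tested regions, so that higher calls stay higher under them follows from the scaling. With TMM, 5511 of the 9604 lower regions were also called lower. Scaling to the total in regions moved the median log2 fold change of all regions by 0.12, from -0.09 to 0.03. The authors' deposited table called 9249 regions, 2033 higher and 7216 lower, and 97.7% of them were called here in the same direction. The number of regions changed in accessibility fell to 5608 without control replicate 1, to 5512 without control replicate 2 and to 6605 without control replicate 3.

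**Figure D2:**
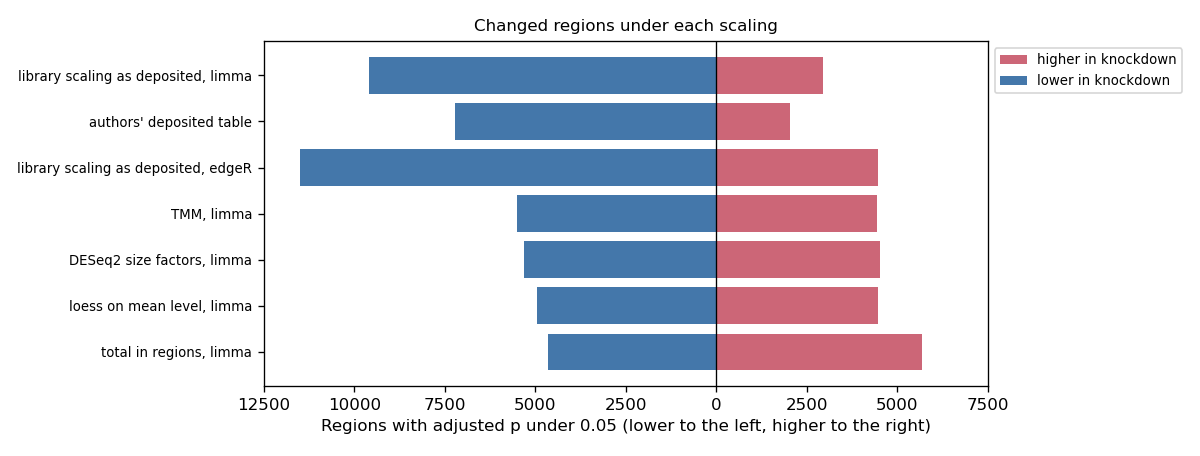
Number of regions called lower (blue, to the left) and higher (red, to the right) in the knockdown at an adjusted p under 0.05, for each scaling and test. At the deposited scaling 9604 regions were lower and 2930 higher, and with TMM factors the numbers were 5511 and 4438.

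The lower regions named by size or p all lay more than 1 kb from a gene end. The region with the smallest p lay within JADE2, which encodes a PHD finger protein (hg38 chromosome 5, 134539796 to 134539996), and fell from 232 ± 26.1 to 73.7 ± 14.6 normalized reads (log2 fold change -1.65 ± 0.13 SE, limma adjusted p = 2.91e-09, n = 4 each). A region within LIMD1 on chromosome 3 (45673329 to 45673529) fell from 93.2 to 28.4, and an intergenic region 14789 bp from the nearest end of RASGEF1B on chromosome 4 (81486596 to 81486796) fell from 66.5 to 19.2. The intergenic regions nearest to BUD13 and C3orf85 fell from 109 to 38.7 and from 118 to 42.1. Among lower regions that averaged at least 20 in the controls and whose groups did not overlap, with 1 region per gene, the largest log2 fold changes were -1.95 within TPD52L2, -1.88 near RGMA, which encodes a repulsive guidance molecule, and -1.86 near GRAMD1A. Their knockdown means were 5.32, 7.59 and 5.83, close to the normalized value of 3 reads (2.15 to 4.62 across libraries). The authors' deposited log2 fold changes of these regions were smaller, -0.72, -0.93 and -0.68. Regions near F2RL1, SPDYE21, MARCO and PRNP and within LRRC8A and GRIA3 fell by between 1.72 and 1.74 on the log2 scale, to knockdown means of 5.84 (PRNP) to 16.7 (F2RL1). The lowest knockdown libraries had 1.34 within LRRC8A and 1.47 within GRIA3, the value of 1 read. A nearest gene is given as a position only, since no link between a region and a gene was measured.

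Among the higher regions, the smallest p belonged to an intergenic region 430769 bp from the nearest end of NRG3 (chromosome 10, 81444325 to 81444525), which rose from 35.8 ± 12.8 to 88.2 ± 13.9 normalized reads (log2 fold change 1.32 ± 0.18 SE, limma adjusted p = 1.45e-05, n = 4 each). Regions near ANKRD18B and PAPPA rose from 27.1 to 62.2 and from 22.02 to 55.7, a region near CELF2 from 45.2 to 88.8 and a region within PIAS2, which encodes a SUMO ligase, from 34.5 to 71.1. The largest rise, 1.74 on the log2 scale, was within UBAC1 (chromosome 9, 135951998 to 135952198), from 6.16 ± 2.69 to 21.4 ± 2.75. Regions near LOC128966717, GUCY2F, IL7, FST (the activin antagonist follistatin), GRP, TBX19, ZNF608 and ADCY9 and within BACH2 rose by between 1.43 and 1.66. Their control means were low, from 5.81 (LOC128966717) to 10.6 (ZNF608), where 3 reads have a normalized value of 2.15 to 4.62 across libraries. Of the higher intergenic regions named, the one near FST was the closest to a gene end, at 3684 bp. Every region named by size or p, higher or lower, kept its call when any single library was left out, and the lower ones also with each of the 4 other scalings. These regions were picked from the same data for large changes or small p, which favours keeping a call, so this is no independent check.

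Regions within 1 kb of an end of a protein-coding gene were called lower more often than other regions, but not once mean level was taken into account. Of 14717 such regions 1923 (13.1%) were lower and 274 (1.86%) higher, against 5.99% and 2.07% of the other regions (Fisher's exact test across regions, which are not independent replicates, odds ratio of a lower call 2.36, 95% interval 2.23 to 2.49). These regions were also stronger, with a median normalized count of 94.4 against 21.7 for regions inside genes and 22.9 for regions between genes. Compared within deciles of mean level, a comparison chosen after the data were seen, the odds ratio was 0.760 (95% interval 0.713 to 0.810). Their mean level relative to other regions differed by -0.02 on the log2 scale (exact permutation p = 0.914, n = 4 each). The balance at gene ends depended on the scaling: 470 were higher and 1024 lower with TMM factors, 482 and 960 with DESeq2 size factors, 674 and 946 with totals in regions and 627 and 459 with loess scaling on mean level, where the odds ratio was 0.885. Where a lower call also required a fall of at least 1 on the log2 scale, its odds ratio over all tested regions was 0.265.

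HOX genes, the homeobox genes that set position along the body axis, stood apart from the other gene lists. Of 39 HOX genes 30 had a tested region at a gene end, and 7 rose and 0 fell over all regions, with 23 higher when adjusted over the list alone. HOXD3 and HOXD4 share a region, as do HOXD10 and HOXD11, so these genes stand for 28 regions, of which 7 were higher over all regions and 21 adjusted over the 28. The 7 became 13 with TMM factors, 15 with DESeq2 size factors, 20 with totals in regions, 13 with loess scaling, 12 without knockdown replicate 1 and 4 after thinning to equal depth, with 0 lower in each; the rise in number with the scalings follows from their upward shift. The median log2 fold change was 0.52 against -0.12 for all gene-end regions, and all 30 members lay above that background. That background is pulled down by strong regions. Gene ends in the strongest decile of mean level had a median of -0.22. Those in deciles 6 to 9 had medians of 0.01 to 0.11. The HOX members were weaker than gene ends on average and were not compared at equal level. With loess scaling on mean level the HOX median relative to all gene-end regions was 0.540, against 0.645 at the deposited scaling. The gene-end region of HOXA6 (chromosome 7, 27147858 to 27148058) rose from 20.2 ± 1.24 to 45.1 ± 6.56 (log2 fold change 1.11 ± 0.18 SE, limma adjusted p = 2.18e-04, n = 4 each). HOXA2 rose from 24.5 to 42.4, HOXA9 from 42.0 to 69.8 and HOXB9 from 59.1 to 87.0. HOXC8, HOXD9 and HOXD8, named after their values were seen because they complete the called members, rose by 0.92, 0.64 and 0.62 on the log2 scale. The list passed camera with a preset correlation (limma camera, Benjamini-Hochberg adjusted p = 5.15e-17), and with an estimated correlation its adjusted p was 0.0857; with each region counted once, a choice made after the data were seen, these were 7.70e-16 and 0.0914. Its level relative to all gene-end regions was higher in the 4 knockdown libraries than in the 4 controls (exact permutation p = 0.0286, adjusted over 15 lists 0.143). The call of HOXB9 was lost without control replicate 3 (limma adjusted p = 0.0603).

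The rise extended over all 4 clusters. Of 105 tested regions between the outermost listed genes, 23 were higher, 1 was lower and 95 had a positive log2 fold change. The number called higher was 6 of 25 in HOXA, 6 of 30 in HOXB, 7 of 29 in HOXC and 4 of 21 in HOXD, and the single lower region lay in HOXD (chromosome 2, 176097593 to 176097793, log2 fold change -0.36, named after its value was seen). Relative to all regions, the mean level rose by 0.50 in HOXA, 0.56 in HOXB, 0.54 in HOXC and 0.40 in HOXD on the log2 scale, each with an exact permutation p of 0.0286 (n = 4 each). Whole clusters were tested after the list's values were seen, and they include the gene-end regions that prompted the test. With gene ends left out, also after the data were seen, 15 of 67 regions were higher and 1 lower, and the mean level rose by 0.51, 0.51, 0.54 and 0.31 in HOXA to HOXD (exact permutation p = 0.0286 each, n = 4 each). HOX cluster regions higher numbered 13, 10 and 13 without control replicates 1, 2 and 3, 37 without knockdown replicate 1 and 11 after thinning to equal depth, and 36 to 53 with the other scalings, which shift all regions up.

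**Figure D3:**
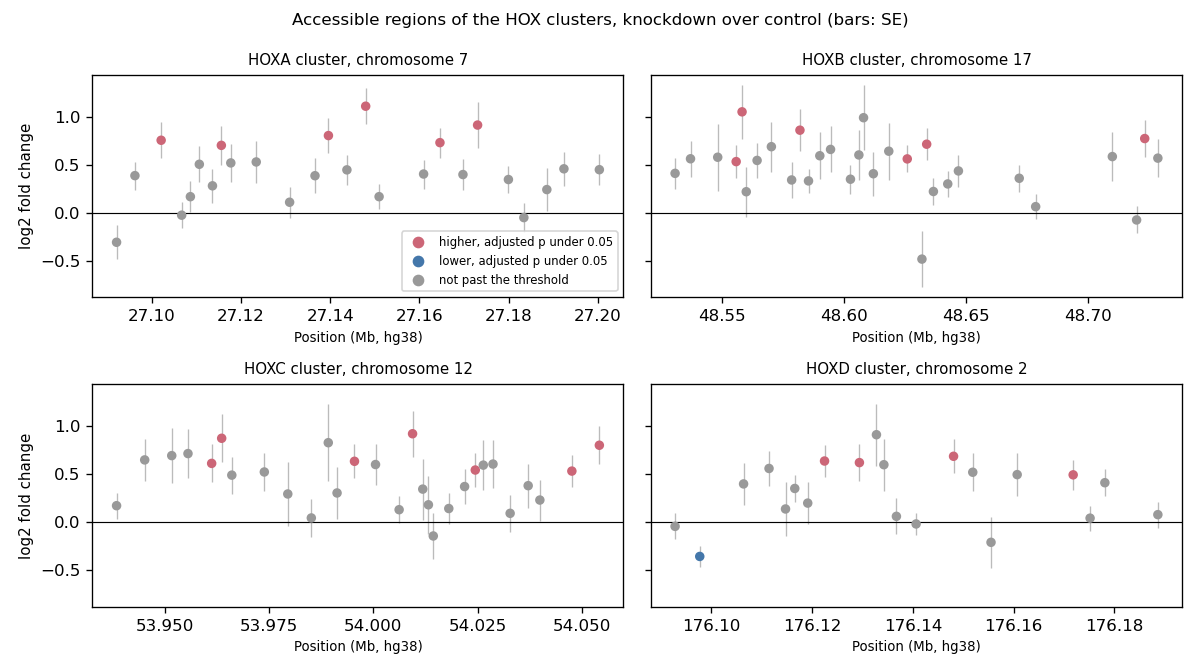
Log2 fold change, knockdown over control, of each tested region (points, bars SE) along the 4 HOX clusters, with position in Mb of hg38. Red points are the 23 regions called higher, the blue point the 1 called lower, and grey points were not called; 95 of 105 lie above 0.

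Some genes of pluripotency and early development were called. No gene-end region could be tested for 6 of 12 core, 5 of 22 naive, 7 of 18 primed and 18 of 28 8-cell genes. Of all genes with a tested gene-end region, 15.01% were lower and 1.84% higher. None of these lists passed camera with the preset correlation (limma camera adjusted p = 0.299 for core, 0.454 for naive, 0.556 for primed and 0.573 for 8-cell genes). Of 6 tested core pluripotency genes 2 fell, PRDM14, a transcriptional regulator of the pluripotent state, from 182 to 126 and L1TD1, which encodes an RNA-binding protein derived from LINE1, from 195 to 147; 4 fell when adjusted over the list alone. TERF1 and CRIPTO, with log2 fold changes of -0.32 and -0.35, passed over the list alone but not over all regions (limma adjusted p = 0.0532 and 0.0781). With loess scaling TERF1 lay just above 0. ZFP42 (-0.16) and NANOG (0.05), named after their values were seen, were not called. Relative to all gene-end regions the means of the core and primed lists differed by -0.18 and -0.14 (exact permutation p = 0.0286 each, n = 4 each, adjusted over 15 lists 0.143). Level was not matched here, and gene ends in the strongest decile of mean level had a median log2 fold change of -0.22. Of 17 naive pluripotency genes 1 rose and 3 fell, both over all regions and adjusted over the list alone: KLF17, a marker of the naive state, rose from 19.4 to 31.4, and DPPA2, DPPA4 and HORMAD1 fell by 0.38, 0.45 and 0.40 on the log2 scale. Of 11 primed pluripotency genes FZD5 fell from 224 to 160 and CD24 from 17.7 to 8.24, with 3 lower adjusted over the list alone. Of 10 genes of genome activation in the 8-cell embryo ZSCAN4 rose from 80.5 to 108 and CCNA1 fell from 220 to 144; 1 rose and 2 fell adjusted over the list alone. With loess scaling on mean level, 0 of the 2 core and 0 of the 3 naive genes were still called lower, FZD5 lost its call, and CCNA1 kept its call. Leaving out single libraries ended several of these calls: KLF17 and ZSCAN4 in 6 of 8 removals (limma adjusted p up to 0.168 without control replicate 1 and 0.169 without control replicate 2), DPPA4 in 6, CD24 in 5, DPPA2 and HORMAD1 in 4, with adjusted p up to 0.163, 0.146, 0.0978 and 0.130 in limma, and L1TD1 without control replicate 1 or 4 (up to 0.0674).

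Most genes of growth and stress were not called. At the deposited scaling more of those called fell than rose in each list, as among all genes with a tested gene-end region, of which 15.01% were lower and 1.84% higher. Of 24 p53 targets 2 rose (CDKN1A and BAX) and 6 fell, with 3 and 10 adjusted over the list alone. These values are of regions at either end of a gene, so a 3' end is not told apart from a promoter. The region of CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 19.5 ± 6.21 to 42.5 ± 6.36 (log2 fold change 1.11, limma adjusted p = 7.67e-04, n = 4 each). Those of GADD45A, RRM2B and CCNG1 fell from 360 to 196, from 284 to 196 and from 316 to 217. Of 16 integrated stress response genes MTHFD2, DDIT4, CHAC1 and PSAT1 fell, by 0.57, 0.53, 0.42 and 0.34 on the log2 scale, with 5 lower adjusted over the list alone. Of 40 genes of RNA polymerase I and ribosome biogenesis 1 rose and 5 fell, as many as adjusted over the list alone: the nucleolar factors NOLC1, RRS1 and RRP9 fell by 0.57, 0.45 and 0.39 and the polymerase subunit gene POLR1D by 0.55. The remaining called members, BOP1 (0.67) and DKC1 (-0.40), and the ribosomal protein gene that rose, RPL7A (0.46), were named after their values were seen, as was BAX (0.62). Of 69 cytosolic ribosomal protein genes 1 rose and 9 fell, among them RPL27A from 275 to 169, RPL41 from 248 to 163, RPL32 and RPL26, with 13 lower and 1 higher adjusted over the list alone. With loess scaling 3 p53 targets were higher and 1 lower, 0 and 1 stress response genes, 2 and 1 ribosome biogenesis genes and 2 and 3 ribosomal protein genes, so the balance turned in 2 of these lists. The calls of CHAC1 and PSAT1 were each lost in 5 of 8 removals of a single library and that of RRP9 in 3 (limma adjusted p up to 0.104, 0.116 and 0.0562). The ribosomal protein list had a median of 0.03 and a mean of -0.01 relative to all gene-end regions, of opposite sign.

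In the remaining lists few genes were called. Of 18 LINE1 and heterochromatin regulators MPHOSPH8, a subunit of the HUSH silencing complex, fell from 285 to 207 and CBX5, which encodes HP1 alpha, from 275 to 212; with loess scaling neither was called, and CBX5 lost its call without control replicate 3 or 4 (limma adjusted p up to 0.0675). Of 15 nuclear lamina and tethering genes EMD, which encodes emerin, fell from 151 to 102, with 1 higher and 5 lower adjusted over the list alone. Of 11 mesoderm genes FOXF1 rose from 37.3 to 58.6, MSGN1 rose from 36.1 to 51.3 and TBX6 fell from 226 to 179; MSGN1 and TBX6 each lost their call in 7 of 8 removals (limma adjusted p up to 0.185 and 0.119). In the heterochromatin list 3 fell, and in the mesoderm list 2 rose and 1 fell, adjusted over the list alone. None of the 13 tested trophoblast, 10 tested hypoblast and endoderm and 8 tested neural ectoderm genes passed limma's test at the deposited scaling, over all regions or adjusted over the list alone. These lists hold 18, 15 and 12 genes, and the remaining genes had no tested gene-end region. TFAP2A (-0.54), FOXA1 (0.33) and NEUROG2 (0.36) had the smallest p of each list, and 3, 1 and 4 genes of these lists had an unadjusted p under 0.05. With other scalings limma called genes of these lists higher and 0 lower: in trophoblast 1 with totals in regions and 1 with loess, in hypoblast and endoderm 1 each with DESeq2 size factors, totals and loess, and in neural ectoderm 2 with totals and 1 each with TMM factors, DESeq2 size factors and loess. Of the 4 genes with the smallest p in each of these lists, KRT7, FOXA1, NEUROG2 and SOX1 passed with edgeR and TMM factors on the recovered reads and TFAP2A with edgeR at the deposited scaling. With TMM factors in limma, which moved the median of all regions by 0.08, L1TD1 (-0.32), DPPA2 (-0.30), DPPA4 (-0.36), HORMAD1 (-0.32), CHAC1 (-0.33), PSAT1 (-0.25), RRP9 (-0.31), CBX5 (-0.29) and TBX6 (-0.24) were no longer called. With the preset correlation no list other than the HOX genes passed camera, and with an estimated one the HOX list did not pass either (adjusted p = 0.0857). The preset adjusted p of the other lists ranged from 0.252 for neural ectoderm to 0.981 for RNA polymerase I and ribosome biogenesis; neural ectoderm passed when a mean of at least 50 was required, but not there with an estimated correlation (camera adjusted p = 0.594). The test fry, which asks whether a list moved at all and not whether it moved apart from other genes, passed for the HOX list, upward, and the core pluripotency list, downward (limma fry adjusted p = 0.0179 and 0.0203), where all gene-end regions had a median of -0.12. Its form for movement in either direction passed for 14 of 15 lists, all but hypoblast and endoderm (limma fry adjusted p = 0.419), and so does not set lists apart.

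**Figure D4:**
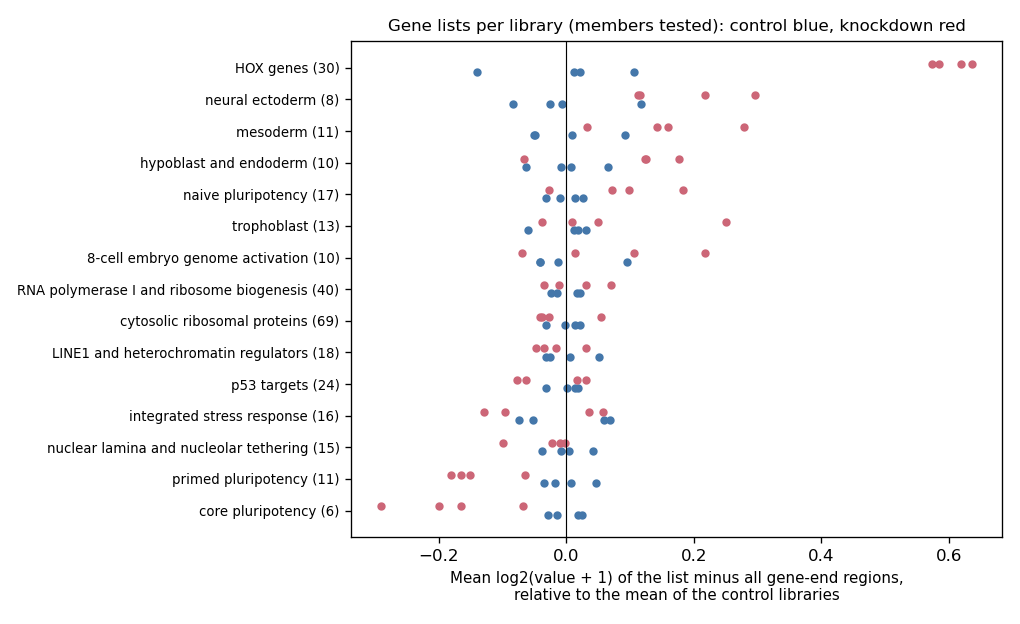
Mean log2(value + 1) of each gene list minus that of all gene-end regions in each library, relative to the mean of the 4 control libraries (controls blue, knockdown red, tested members in brackets). The HOX genes lie 0.60 higher on average in the knockdown, with all 4 knockdown libraries above the 4 controls.

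The ribosomal DNA arrays lie on the short arms of the acrocentric chromosomes 13, 14, 15, 21 and 22. Over the 15964 tested regions of these chromosomes, the mean log2 level relative to the other autosomes was -0.02 ± 0.02 in the controls and -0.005 ± 0.008 in the knockdown (n = 4 each), a difference of 0.018 (exact permutation p = 0.114). Over the 2414 regions that start below 30 Mb it was 0.040 ± 0.033 and 0.060 ± 0.017 (exact permutation p = 0.371, n = 4 each). Of the acrocentric regions 2.20% were higher and 6.09% lower, against 2.08% and 6.64% on the other autosomes. Without control replicate 4 the difference over whole chromosomes was 0.025 (exact permutation p = 0.0286). The pooled difference joins shifts of opposite sign. Each against the other autosomes, chromosomes 13 and 14 shifted by -0.038 and -0.002, and 15, 21 and 22 by 0.035, 0.060 and 0.090. The exact permutation p was 0.0286 for 13, 21 and 22, 0.571 for 14 and 0.0857 for 15. None passed the adjustment over the 23 chromosomes. On the short arms of chromosomes 21 and 22 the table held 16 regions, of which 4 were deep enough to test and 0 changed (limma, lowest adjusted p = 0.509, 0 at an unadjusted p under 0.05). Of 74 tested regions on alternate contigs 1 changed, on a contig of chromosome 2, where the level fell from 24.3 to 10.5, a region named after its value was seen.

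Chromosome X showed the largest lower shift. Relative to the autosomes its mean level was 0.01 ± 0.03 in the controls and -0.08 ± 0.02 in the knockdown (exact permutation p = 0.0286, n = 4 each; chromosome X shift -0.08 without knockdown replicate 3, exact permutation p = 0.0571), and 10.3% of its tested regions were lower. Chromosomes 17, 22 and 21 shifted up by 0.10, 0.09 and 0.06 and chromosome 19 by 0.14 (exact permutation p = 0.0571 for chromosome 19; chromosome 19 shift 0.18 without control replicate 4, exact permutation p = 0.0286). After the trend on gene density was removed per library, chromosomes 17, 22, 21 and 19 shifted by 0.07, 0.07, 0.06 and 0.08 and X by -0.08 (exact permutation p = 0.0857 for chromosome 22 and 0.0286 for the others, n = 4 each), and the shift of chromosome 1 went from 0.01 (exact permutation p = 0.0286) to 0.004 (exact permutation p = 0.371). Of the 23 chromosomes 9 then had the smallest p, and the smallest adjusted exact permutation p was 0.0730. Before removal the groups did not overlap for 10 of 23 chromosomes, 5 up and 5 down, where chance gives 2.86%, but none passed the adjustment over the 23 chromosomes (smallest adjusted exact permutation p = 0.0657). Across the 22 autosomes the shift rose with the density of genes around the regions (Pearson r = 0.842, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.769, permutation p = 7e-05). Without chromosomes 19 and 17, the farthest in density, r was 0.762. Chromosomes are not independent replicates. The control libraries differed along the same axis: in the most gene-dense regions the mean deviation was -0.11 in control replicate 2 and 0.06 in control replicate 4.

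**Figure D5:**
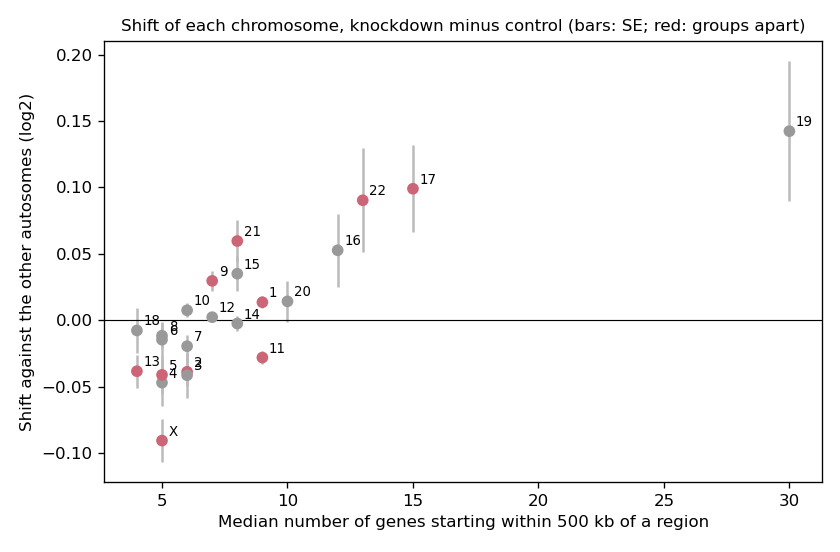
Shift of each chromosome against the other autosomes (vertical axis, log2, knockdown minus control, bars SE over libraries) by the median number of genes near its regions (horizontal axis). Red points mark the 10 chromosomes whose groups did not overlap; X lies lowest at -0.09 and chromosome 19 highest at 0.14.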

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

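Each value below is a library far from the other 3 of its group by Dixon's criterion. It was applied to 272 groups of 4, where chance gives about 13.6, and 10 were found, so their number is no more than chance gives. No explanation was tested for them. The test of whole HOX clusters was chosen only after the result was seen.

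Control replicate 4 stood apart in 4 results. Its level over the HOXA cluster relative to all regions was 0.445, against 0.304 to 0.308 in the other controls and below the 0.84 mean of the knockdown. Its signal near NRG3 was 54.9 normalized reads against 26.95 to 30.8, and at the gene end of RFPL1 it was 142.39 against 130 to 132. The level of chromosome 11 in it was 0.103 against 0.112 to 0.113.

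Knockdown replicate 1, the shallowest library, stood apart in 3 results. Its level over the HOXB cluster was 0.354 against 0.510 to 0.541 in the other knockdown libraries, and over the cytosolic ribosomal protein genes it was 0.325 against 0.229 to 0.243. On chromosome 14 it was 0.0359 against 0.0199 to 0.0225. Control replicate 1 had 30.9 normalized reads within LRRC8A against 20.8 to 22.1 and 240.19 at POLR1D against 247.86 to 248.32. Knockdown replicate 2 had 104.2 normalized reads near CELF2 against 82.8 to 84.7.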

How the results depend on the processing

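TMM factors, thinning, the gene density trend, the edgeR tests, the authors' table and 2 kb lists were chosen after seeing the data, as were settings applied beyond the result they were planned for. Of the 65 named calls 18 were lost with loess, 9 with TMM and 0 with edgeR at the deposited scaling, and none of the lower calls turned. Causes were not tested unless stated. The counts are, in order, of regions higher and regions lower: 4507 and 5304 with DESeq2 size factors, 5674 and 4639 with totals in regions, 4475 and 4957 with loess and 4438 and 5511 with TMM; removal of the gene density trend left 5634 lower. A mean of at least 50 gave 7241 regions changed in accessibility with 702 higher (fewer regions tested). An adjusted p under 0.01 gave 4453 (690 higher, 3763 lower), a log2 fold of at least 1 gave 1793 (616 and 1177), thinning to equal depth 7844 (1630 and 6214) and the DESeq2 Wald test 6818 (1157 and 5661). The edgeR tests called 6629 higher with TMM and 4469 at the deposited scaling. The number of promoter regions changed (gene ends) was 2197, and 1442 with DESeq2 size factors, 1086 with loess, 948 at an adjusted p under 0.01 and 60 at a log2 fold of at least 1; the odds ratio of a lower call there turned to 0.885 with loess and 0.265 at that fold.

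Over alternate contigs and the short arms of chromosomes 21 and 22 together, changed regions went from 1 to 2 with totals in regions, loess, thinning and both edgeR tests and to 0 with the DESeq2 Wald test. Camera passed 2 lists at a mean of at least 50 (HOX and gene list, neural ectoderm, adjusted p = 0.0222; 0.185 and 0.594 there with an estimated correlation) and 0 with an estimated correlation at the usual mean, where the HOX mean stayed 0.604 (adjusted p = 0.0857; 2.78e-17 to 4.64e-09 with the preset one, the replicate block aside). Lists and genes not called turned sign near 0 (mean of each gene list, relative): gene list, p53 targets to 0.0188 with loess, 0.00243 with thinning, 0.0428 with all gene-end regions and 0.0104 within 2 kb; gene list, cytosolic ribosomal proteins to 0.00128 with loess and 0.0256 at a mean of at least 50; gene list, LINE1 and heterochromatin regulators to 0.0247 at that mean; gene list, RNA polymerase I and ribosome biogenesis to -0.0274 with all gene-end regions; region APOA1 chr11_116835993 to 0.0234 with totals and 0.0747 with loess; region TERF1 chr8_73008661 to 0.00345 with loess.

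Leaving out each library gave 5512 to 15580 regions changed in accessibility, 1094 to 3887 for regions higher, 4418 to 11693 for regions lower and 1089 to 2560 promoter regions changed, with 5608, 5512 and 6605 changed without control replicates 1, 2 and 3. Changed regions on alternate contigs and these short arms ranged from 1 to 2, the odds ratio of a lower call at gene ends from 1.86 to 3.13, the acrocentric difference from 0.0128 to 0.0250 and the HOX mean from 0.557 to 0.639. The log2 fold change of region GATA4 chr8_11759583 ranged from -0.322 to 0.00745 (without knockdown replicate 4), gene list, RNA polymerase I and ribosome biogenesis from -0.00545 (without knockdown replicate 1) to 0.0299 and gene list, LINE1 and heterochromatin regulators from -0.0327 to 2.55e-04 (without control replicate 4). Of 65 called named regions 51 kept their call in all 8 removals.

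The numbers do not pair the libraries: same-numbered deviations correlated by 0.018, -0.015, -0.036 and 0.030, and 1 of 4 controls correlated best with its own number. With the replicate block, regions changed in accessibility numbered 12588, regions higher 3046 and regions lower 9542, and 3 of 65 named calls were lost (PSAT1, TBX6, MSGN1). DESeq2 gave no adjusted p for 18 of the 65. Correction for GC content and the LINE1 repeat comparison were not run. Depth limits the number of calls, which fell from 12534 to 7844 with thinning to equal depth. In simulated data at the real depths with 200 changed regions, 22% of falls to 0.667 were called, a rate that does not carry over to the real fit.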

Other observations

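The distal regions, thinning, removal of the gene density trend and the test with TMM factors were chosen only after results were seen. Distal regions gave a further view of the fixed lists, over regions inside or within 50 kb of each gene with gene ends left out. Around the HOX genes 20 of 105 distal regions were higher and 3 lower (limma camera adjusted p = 5.5e-16, and 0.102 with an estimated correlation). These include the 67 cluster regions without gene ends already given, of which 15 were higher and 1 lower, so most of this result is not new. Around core pluripotency genes 1 of 132 was higher and 19 were lower, with a median log2 fold change of -0.27 against -0.09 for all distal regions (camera adjusted p = 7.01e-04, and adjusted p = 0.254 with an estimated correlation). Around naive pluripotency genes 2 of 207 were higher and 19 lower (camera adjusted p = 0.411).

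Of the homeobox, PAX, FOX, SOX, TBX, GATA and WNT genes outside the HOX clusters, 144 had a tested gene-end region. Of these genes 9 were higher and 10 lower, and 96 lay above the median of all gene-end regions (camera p = 3.85e-06 with a preset correlation and p = 0.215 with an estimated one). WNT10A and WNT6 share a higher region, which is counted for both genes. UNCX, DLX3 and PBX3 rose by 1.26, 0.85 and 0.84 on the log2 scale, and SOX10 and WNT8A had log2 fold changes of -0.93 and -1.12; these genes were picked after their values were seen.

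After the trend on gene density was removed per library, the HOX median relative to all gene-end regions was 0.636, against 0.645 before and a limit of 0.323. After thinning every library to the depth of the shallowest it was 0.570, which argues against the lower depth of the knockdown within these regions as the whole cause. Developmental genes as a class may rise too: the other families had a median of 0.186, above the limit of 0.161 that would have set them apart, while camera with an estimated correlation gave p = 0.215, so this stays open. Neither this median nor that of the HOX genes was compared with gene ends of equal mean level. GC content was not tested and stays open too, and an effect of the knockdown on HOX chromatin remains a hypothesis. Of 35 splits of the 8 libraries 17 passed at least as many lists as the real split (1 list, highest other 3), but the 16 others all kept 3 of 4 libraries of each group together and the 18 that divided both groups evenly passed 0, so this count does not decide about chance; the HOX mean of 0.604 was the largest of the 35 (highest other 0.370, and 0.0884 in the even splits).

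The excess of lower calls at gene ends was gone with loess scaling on mean level, where the odds ratio of a lower call was 0.885 (95% interval 0.801 to 0.976). Gene-end regions are the strong regions, though, and loess centres strong regions by construction, so a weaker contrast between strong and weak regions in the knockdown libraries, which may be technical, and a shared fall at strong regions cannot be told apart. At the deposited scaling 23.9% of gene-end regions and 22.4% of other regions in the strongest decile of tested regions were lower, and 2.57% and 11.7% in the next decile (odds ratio over all deciles 0.760, 95% interval 0.713 to 0.810), a comparison chosen after the data were seen, so at equal level gene ends were not called lower more often over all deciles. Knockdown replicate 1, with the weakest contrast, was not the sole source, since without it the odds ratio was 1.99 (1.89 to 2.09). For the number of changed gene-end regions, 1 of 35 splits, the real one, gave as many (2197, highest other 0). That is the smallest share that 35 splits allow. The other splits mix the groups, which puts any difference between the groups into their spread and lowers their counts, so chance is not excluded.

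The preponderance of lower regions was set against depth and scaling. With all libraries thinned to equal depth 20.8% of changed regions were higher, so unequal depth of the reads within these regions does not account for it. Thinning kept the deposited set of regions, so an effect of depth on which regions were called could not be tested. With TMM factors 44.6% were higher, but TMM centres the bulk of regions and so pulls the share toward balance by construction; a general fall in accessibility and the scaling to library totals cannot be told apart without an external standard. For the number of changed regions, 1 of 35 splits, the real one, gave as many (12534, highest other 21). Here too 35 splits allow no smaller share and the other splits mix the groups, so chance is not excluded.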
